A study of Mus musculus with 1615 samples.

How the data were processed

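Single T cells from mouse germinal centers, the sites in lymphoid tissue where B cells are selected with T cell help, were index-sorted into 96-well plates, and a Smart-seq2 library was made from each cell. The series holds 1615 cells on 19 plates from 5 experiments. Smart-seq2 reads the whole transcript and carries no molecular identifiers, so each value counts reads after PCR, not molecules. The deposited values are expected counts, estimates of the number of reads per gene and cell that are not scaled to depth. Between 72.9% and 81.1% of the non-zero values in a file were exactly whole, counted with no tolerance. The labels name the mouse build mm10 and the tools STAR 2.6, RSEM 1.3.1 and Seurat 3.1.4 without saying what each was used for. The values for experiments 1 and 2 are listed by Ensembl identifier, with 1 further row for an added Foxp3 sequence. In the values for experiments 3 and 4, 55094 of 55487 identifiers matched the version in the reference annotation for GRCm38, and the values for experiment 5 carry gene symbols only. Experiments 1 to 4 were joined on 55394 shared genes.

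The columns of the files are named by experiment, plate and well, and the labels give each cell's plate and class but no well. The classes that the labels give (Tfh1, Tfh2, Tfr, CD4+ Resting, CD8+, Cycling and Filtered cell) are therefore known as numbers of cells per plate and not cell by cell. Comparisons planned between these classes were made between classes of cells clustered from marker genes that were fixed before the data were examined, each named with the ending -like. The comparison of cells with ectopic Foxp3 and control cells in experiment 5 was not made, since its columns cannot be given to either group.

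Cells of experiments 1 to 4 were kept when they had at least 500 genes, at least 20000 reads, a read in Cd3e, Cd3d, Cd3g or Trac, and no read in Cd79a, a part of the B cell receptor. The last filter was aimed at wells with B cell RNA. Ighm still had a read in 55.0% to 80.2% of the kept cells of each class, and Cd79b in 1.35% to 11.8%. Whether the Ighm reads come from B cells was not tested. Of 1396 cells, 1057 were kept (75.7%). Depth removed 149 cells, the T cell genes removed 53 and Cd79a removed 137. No other search for wells with more than 1 cell was made. The thresholds and the settings of the clustering were chosen after the data had been seen, from 9 combinations of thresholds and 6 settings.

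The clustering used 117 of the fixed marker genes, those found in at least 2% of kept cells, and left Foxp3 out. Values were taken as log2 of depth-scaled counts (CPM) divided by 100 plus 1, scaled within each experiment, reduced to 12 principal components and clustered by the Leiden method at resolution 0.5 on 15 neighbours (Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, scipy 1.17.1). Each cluster was named after the fixed marker list with the highest mean score in it, unless more of its 10 leading genes came from another list, and of the 2 clusters with Tfh markers the one with the higher Tfh score was called Tfh-like B. The clustering genes were left out of every gene count. Genes that vary with them from cell to cell differ between the classes by construction, so a p-value here does not say whether the classes exist.

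Cells are not replicates. The labels name no animals, and the smallest units they separate are experiments 1, 2 and 3 and the 2 strains of experiment 4, which gave 5 units. Plate 13 holds both strains and was left out of the 5 units of the clustered classes. The labels give the strain of each cell, so the shares of labelled classes include plate 13. Counts were summed over the cells of a class within a unit, with at least 5 cells per sum. Resting-like and CD8-like cells reached this number in 4 units. Summed counts were compared with edgeR 4.0.16 (R 4.3.3, quasi-likelihood F test, TMM factors, filterByExpr) with the unit as a block, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The classes of a unit come from the same plates, but in unequal numbers. In experiment 1, plate 1 held 41 of 72 Tfr-like, 31 of 45 resting-like and 3 of 158 Tfh-like cells. Class and plate are therefore partly confounded there. With no replicate block, the 4 comparisons gave 4, 0, 21 and 0 genes in the order Tfr-like against Tfh-like, Tfh-like B against A, resting-like against Tfh-like and Tfr-like against resting-like. On simulated counts with the estimated spread, edgeR recovered 10%, 11%, 0% and 0% of 4-fold changes in these comparisons.

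Because of that low recovery, a further test was added after the edgeR results were seen. Each cell was thinned to 50000 reads, which left out 27 cells, and the share of cells with at least 1 read was taken per class and unit for genes found in at least 10% of cells on average. The arcsine square root of the shares was compared with limma 3.58.1 (trend, unit as a block, weights equal to the number of cells), and repeated with each sum centred on its median gene. With no replicate block this test called 87, 46, 89 and 5 genes in the same order. On simulated shares it recovered all of the changes of 30 points in 3 comparisons and 99.0% in Tfr-like against resting-like, and between 10.4% and 63.3% of changes of 10 points. In that simulation both classes of a unit shared the unit effect, so class differences varied between units only through the drawing of cells. The recovery therefore does not cover differences that vary between units. In every comparison limma replaced each gene's own spread over units with a spread pooled over genes. Its small p-values rest on that spread and on the weights, and do not measure how steadily a single gene recurred across units. Without the weights it called 208, 167, 692 and 103 genes.

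The rule fixed for named genes was to take, per direction, the 10 largest changes among genes past the threshold with the same sign in every unit and a mean log2 CPM of at least 5, leaving out receptor segments and unnamed gene models. It named no gene by edgeR. The same rule, with the 10% of cells in place of the CPM minimum, was then applied to the shares of cells, for genes past the threshold both with and without centring. Of the genes it gave, 1 is not reported here. Foxp3, Bcl6, Cxcr5, Pdcd1, Icos, Il21, Il4, Ctla4, Il2ra and Cd40lg were named in advance. The lists of helper cytokines and of inhibitory receptors kept 1 or 2 members and had no test of their own. Another 6 gene lists fixed in advance kept enough members outside the clustering to be tested (IL-2 and STAT5 response, T cell receptor signalling, interferon response, glycolysis and hypoxia, migration and adhesion, immediate early genes), with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison.

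Shares of cells with Foxp3 were compared by exact sign-flip permutation tests over units, two-sided, which cannot go below p = 0.0625 with 5 units or p = 0.125 with 4. Shares per plate were related over 15 plates by Pearson's r and Spearman's rho with 100000 permutations. Intervals for shares are exact Clopper-Pearson intervals at 95%, and the limit given for a count of 0 is 3 cells of the total. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. Alternatives covered the normalization, the filter, DESeq2 1.42.0, the block, means of CPM per cell, thinning, 4 units, each unit left out, the Cd79a filter, the clustering resolution, and plate 1 of experiment 1 left out. Figures were drawn with matplotlib 3.10.9.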

Results

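The series asks which T cells of the mouse germinal center express Foxp3, the transcription factor of regulatory T cells, and what single germinal center T cells look like when Foxp3 is expressed ectopically. RNA was sequenced from 1615 single T cells. Experiments 1 to 4 hold 1396 cells, of 384, 383, 254 and 375 cells in turn. They came from mice that carry a Foxp3 reporter, of the strain PA-GFP Foxp3IRES-RFP in experiments 1 to 3 and of this strain and dsRed Foxp3IRES-GFP in experiment 4. Experiment 5 holds 219 cells of the strain OT-II CD4-Cre-ERT2 Rosa26Foxp3, of which the labels give 110 as ectopic Foxp3 cells and 109 as controls. The median number of reads per cell was 326355, 142627, 336533, 219365 and 313828 in experiments 1 to 5. The 1057 cells kept from experiments 1 to 4 had a median of 2476, 1855, 1568 and 1560 genes.

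The labels divide 968 cells of experiments 1 to 4 into 6 classes and mark 428 cells as filtered. The classes are 2 kinds of follicular helper cells (Tfh1, 328 cells, and Tfh2, 233 cells), follicular regulatory cells (Tfr, 156 cells), resting CD4 cells (161 cells), CD8 cells (63 cells) and cycling cells (27 cells). Over the 5 units of experiment and strain, Tfh1 cells made up 35.2% ± 9.80 (SD, n = 5) of the cells not filtered, Tfh2 cells 22.9% ± 5.23 and Tfr cells 17.1% ± 3.55. CD4+ Resting cells made up 16% ± 5.38, CD8+ cells 4.74% ± 5.48 and Cycling cells 3.97% ± 3.74. The sort gates are not in the labels and can set these shares. Plate 1 of experiment 1 stood apart, with 51 CD4+ Resting and 17 Tfr cells among its 77 cells not filtered.

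Clustering on fixed markers gave 6 classes of cells, with 371 Tfh-like A, 182 Tfh-like B, 274 Tfr-like, 100 resting-like, 85 CD8-like and 45 cycling-like cells. The classes differed in the genes that defined them, which are given as values without a test. Bcl6, the transcription factor of follicular helper cells, had a read in 79.8% ± 5.98 (SD, n = 5) of Tfh-like B, 57.3% ± 11.5 of Tfh-like A and 20.7% ± 6.56 of Tfr-like cells. The chemokine receptor Cxcr5, which brings T cells to the B cell follicle, had a read in 83.6% ± 9.61, 71.9% ± 11 and 20.1% ± 7.25 of them. Pdcd1 was found in 92.9% ± 3.25, 77.7% ± 4.64 and 23.9% ± 8.96, and Icos in 72.0% ± 17.9, 56.0% ± 5.72 and 56.1% ± 4.38. Il21, a cytokine that acts on B cells, was found in 42.7% ± 7.33 of Tfh-like B, 9.47% ± 3.05 of Tfh-like A and 2.70% ± 2.51 of Tfr-like cells. Il4 was found in 34.8% ± 9.03, 39.3% ± 7.93 and 3.52% ± 2.62, and Cd40lg in 40.4% ± 10.3, 37.5% ± 15.2 and 22.3% ± 14.1. The inhibitory receptor Ctla4 was found in 71.7% ± 13.7 of Tfh-like B, 19.2% ± 5.28 of Tfh-like A and 40.2% ± 15.3 of Tfr-like cells. Il2ra, the high-affinity chain of the IL-2 receptor, was found in 35.3% ± 14.9 of Tfr-like, 3.20% ± 2.81 of Tfh-like A and 2.30% ± 4.35 of Tfh-like B cells.

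Over 15 plates, the share of each labelled class was set against the share of the matching class of cells. Labelled Tfh1 and Tfh2 cells together followed Tfh-like cells (r = 0.908, permutation p = 0.00013; rho = 0.739, p = 0.00233; r = 0.943 within experiments). Tfh1 followed Tfh-like A (r = 0.795, permutation p = 0.00013; rho = 0.795, p = 0.00066; r = 0.741 within experiments). Tfh2 followed Tfh-like B (r = 0.839, permutation p = 8e-05; rho = 0.825, p = 0.0003; r = 0.826 within experiments). Tfr followed Tfr-like cells less closely (r = 0.594, permutation p = 0.0187; rho = 0.602, p = 0.0197; r = 0.591 within experiments). Tfr-like cells were on average 25.9% of a plate where the labels give 16.7% Tfr cells. CD8+ followed CD8-like cells (r = 0.917, permutation p = 4e-05; rho = 0.663, p = 0.00892; r = 0.867 within experiments). Without the 2 plates farthest from the median, r was 0.722 for Tfh, 0.606 for Tfh1, 0.914 for Tfh2, 0.590 for Tfr and 0.876 for CD8+. The relations of CD4+ Resting (r = 0.912, permutation p = 0.00209; rho = 0.504, p = 0.0580) and Cycling (r = 0.905, permutation p = 0.0032; rho = 0.570, p = 0.0289) with their classes rested on the 2 farthest plates, without which r was 0.459 and 0.397. Labelled Tfr cells followed the share of cells with a Foxp3 read within experiments (r = 0.507, p = 0.00565 with plates permuted within experiments, adjusted 0.0113) and without the 2 farthest plates (r = 0.685, p = 0.00293). Over all plates the relation did not pass (r = 0.402, permutation p = 0.134; rho = 0.425, p = 0.117). Adjusted over these 8 relations, p for r was 0.00026 for Tfh, Tfh1, Tfh2 and CD8+, 0.00334 for CD4+ Resting, 0.00427 for Cycling, 0.0214 for Tfr and 0.134 for Foxp3.

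**Figure D1:**
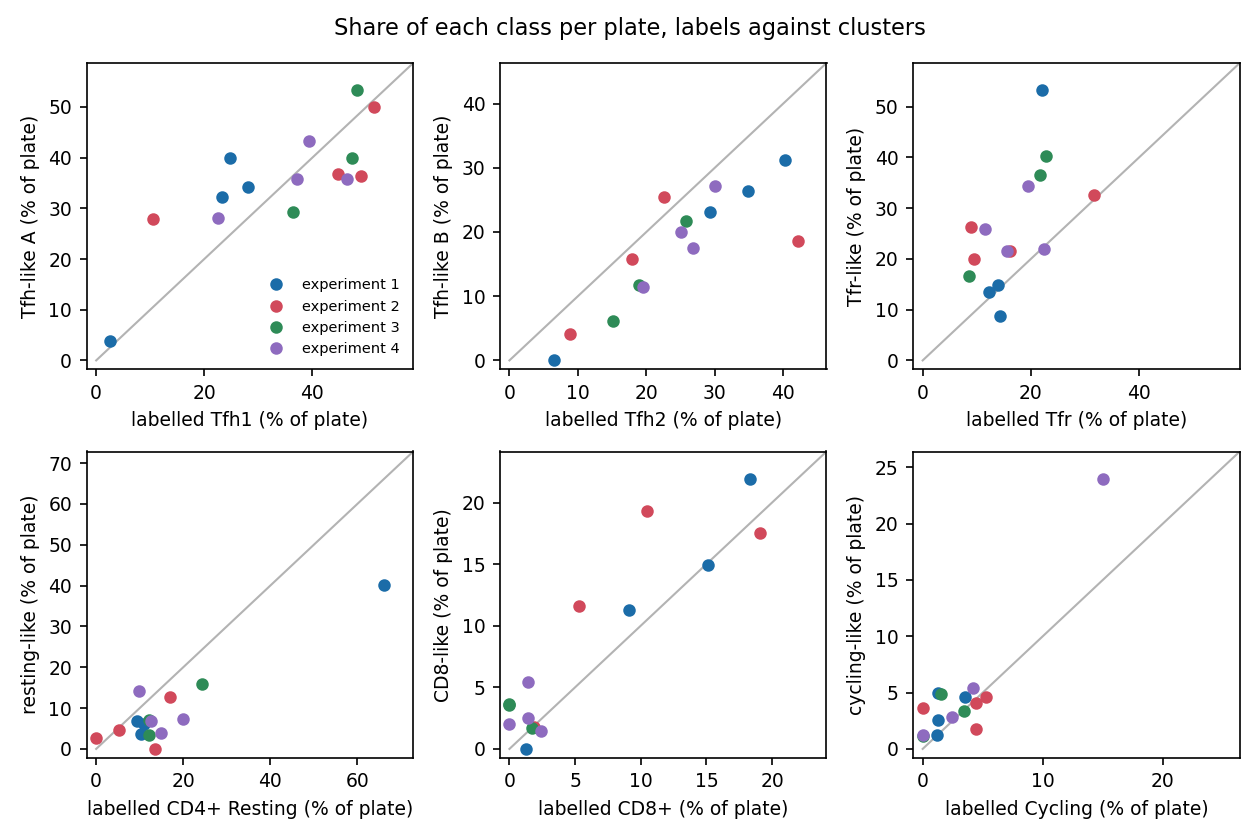
Share of cells of each labelled class (percent of cells not filtered, horizontal axes) against the share of the matching class of cells (percent of kept cells, vertical axes), 1 point per plate, coloured by experiment; the grey line marks equal shares. Points of Tfr-like cells lie mostly above the line (mean 25.9% against 16.7%), and 1 plate of experiment 1 lies far to the right for CD4+ Resting.

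Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, GRCm38) was left out of the clustering. It belongs to the marker list that named the Tfr-like class, however, and was among the 10 leading genes of that cluster. The clustering also used other markers of that list, such as Il2ra and Ikzf4. A larger share of Tfr-like cells with Foxp3 is therefore favoured by construction. It had a read in 143 of 274 Tfr-like cells (52.2%, 95% interval 46.1 to 58.2), in 74 of 553 Tfh-like cells of both kinds (13.4%, 10.7 to 16.5) and in 5 of 85 CD8-like cells (5.88%, 1.94 to 13.2). CD8-like cells serve as the background in experiments 1 and 2, where 37 of 40 and 25 of 30 of them held Cd8a. None of the 7 in experiment 3 and the 6 in the PA-GFP unit of experiment 4 did. The median depth was 302599 reads in Tfr-like, 256128 in Tfh-like and 284212 in CD8-like cells. Summed over cells, Foxp3 reached 233 CPM in Tfr-like, 55.9 CPM in Tfh-like and 1.76 CPM in CD8-like cells. In experiments 1 and 2 alone it was 41.3 CPM in Tfh-like and 0.601 CPM in CD8-like cells, as most Foxp3 reads of CD8-like cells (34.5) came from experiment 3. A Tfh-like cell with Foxp3 had a median of 78.5 reads in the gene, and a CD8-like cell with Foxp3 a median of 2.62. Averaged over units, Foxp3 was found in 51.5% ± 17.9 (SD, n = 5) of Tfr-like cells and 15.9% ± 11 of Tfh-like cells, a difference of 35.6 points ± 11.8 that was positive in 5 of 5 units (exact sign-flip p = 0.0625, adjusted over 4 comparisons 0.125). It was also positive in each of the 14 plates with enough cells, by 35.0 points ± 18.9. With 5 units no difference can fall below p = 0.0625.

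Within the Tfh-like cells, Foxp3 was found in 24.1% ± 20.7 (SD, n = 5) of Tfh-like B and 10.5% ± 5.49 of Tfh-like A cells. The difference of 13.7 points ± 18.2 was positive in 5 of 5 units (exact sign-flip p = 0.0625, adjusted 0.125), and in 10 of 13 plates, with 2 plates at 0 difference and 1 below. The clustering used regulatory markers here too. Of these, Ctla4 and Ikzf2 were found in more Tfh-like B than Tfh-like A cells, and Il2ra and Itgae were not. A larger share of Tfh-like B cells with Foxp3 may therefore also be favoured by construction. The difference fell to 5.65 points ± 3.60 (n = 4) without the dsRed unit of experiment 4, where 6 of 10 Tfh-like B cells had a Foxp3 read. When the cells were clustered at resolution 1, the dsRed unit was left with too few Tfh-like B cells (3). Over the same 4 units the difference was then -7.18 points ± 3.85, below 0 in each. Most of the Tfh-like B cells were named Tfh-like A there, so that value compares other cells under the same names. With Cd79a-positive cells kept, Tfh-like B minus A was 5.85 points and positive in 3 of 5 units (exact sign-flip p = 0.562). With classes from variable genes it was positive in 4 of 5 units. Among all genes tested by shares of cells with limma, Foxp3 was not called between Tfh-like B and A (adjusted p = 0.254). Tfh-like cells exceeded CD8-like cells by 5.43 points ± 6.48 in 3 of 4 units (exact sign-flip p = 0.25, adjusted 0.333; the smallest p possible is 0.125). Resting-like cells had Foxp3 in 19% ± 26.2 (n = 4), 7.49 points ± 20.7 more than Tfh-like cells (exact sign-flip p = 0.625, adjusted 0.625). This value came from plate 1, where 25 of 31 resting-like cells had a Foxp3 read, and without that plate the difference was -5.11 points.

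**Figure D2:**
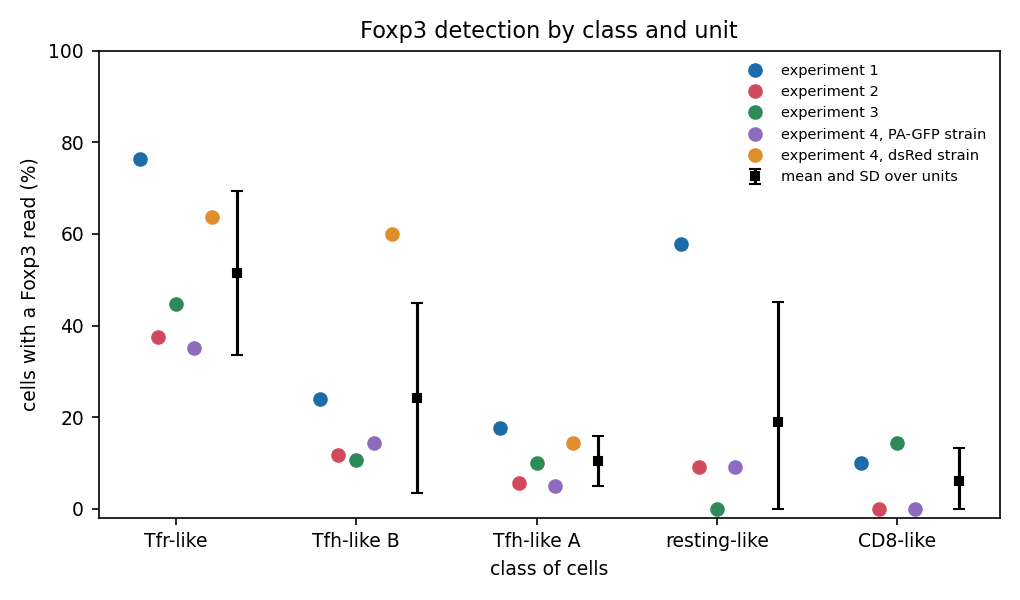
Percent of cells with at least 1 Foxp3 read (vertical axis) in each class of cells (horizontal axis), 1 point per unit of experiment and strain; squares and bars give the mean and SD over units, with the lower end of a bar drawn no lower than 0. Tfr-like cells lie between 35.1% and 76.4%, Tfh-like A cells between 4.92% and 17.6%, and 1 unit each stands apart among Tfh-like B (60%) and resting-like cells (57.8%).

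The comparison of Tfr-like with Tfh-like cells asks how the class with regulatory markers differs from the classes with helper markers. Cxcr5 was found in 20.1% ± 7.25 (n = 5) of Tfr-like and 21.1% ± 5.69 (n = 4) of CD8-like cells. S1pr1, a marker of recirculating cells, was found in 28.5% of Tfr-like and 10.8% of Tfh-like cells. Whether the Tfr-like cells are all follicular was not tested. By share of cells, 465 genes differed both with and without centring, of which 198 were found in more Tfr-like cells and 267 in fewer (limma, 4816 genes tested). Centring alone called 290 in more and 267 in fewer. Selplg, the P-selectin ligand (ENSMUSG00000048163, chromosome 5, 113818536 to 113832644), was found in 53.4% ± 11.3 (SD, n = 5) of Tfr-like and 16.4% ± 4.61 of Tfh-like cells (adjusted p = 2.01e-23). Other genes found in more Tfr-like cells in 5 of 5 units were the membrane-binding protein Anxa6 (47.9% against 8.35%), Foxp3 itself (48.5% against 15.3% of thinned cells), the filament protein Vim (40.5% against 9.12%) and Fam3c (42.5% against 16.3%). Ahnak (33.4% against 8.43%), the integrin chain Itgb7 (48.6% against 25.3%), Sema4b (45.4% against 22.3%), the interferon gamma receptor chain Ifngr1 (35.1% against 12.3%) and S100a10 (67.9% against 46.2%) followed. Hif1a, a transcription factor of the response to low oxygen (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530), was found in 37.1% ± 7.44 of Tfr-like and 77.0% ± 11.8 of Tfh-like cells (adjusted p = 5.09e-23). Further genes found in fewer Tfr-like cells in 5 of 5 units were the G protein subunit Gna13 (19.9% against 58.3%), Art2a (5.26% against 39.9%), Nav2 (17.8% against 51.6%), Tbc1d4 (35.5% against 67.7%) and Dennd2d (28.1% against 59.7%). Asb2 (11.9% against 43.0%), Slc9a9 (22.3% against 53.1%) and Rgs10, a regulator of G protein signalling (59.4% against 89.9%), did likewise. Selplg, Anxa6, Vim and Itgb7 were also found in more resting-like than Tfh-like cells, so they do not single out Tfr-like cells. Hif1a, Nav2 and Tbc1d4 were found in fewer resting-like than Tfh-like cells (20.3%, 2.35% and 5.29% of resting-like cells). Their lower shares do not single out Tfr-like cells either.

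Among the fixed lists, the IL-2 and STAT5 response was higher in Tfr-like cells (camera on sums, adjusted p = 1.51e-06, and adjusted p = 0.0270 with an estimated correlation). By share of cells 3 of its 8 measured members rose, also when adjusted over the list alone, and none fell. They were Cish, which restrains cytokine signalling (20.5% against 1.71%), Pim1 (39.4% against 28.5%) and lymphotoxin Lta (17.7% against 5.79%). The interferon response was higher (adjusted p = 4.10e-05, and 0.0270 with an estimated correlation), with 1 of 12 members past the threshold over all genes, Gbp2 (14.6% against 7.74%), and 2 adjusted over the list alone. Migration and adhesion genes were higher as a list (adjusted p = 0.00175, and 0.0488 with an estimated correlation). Of its 11 members 6 rose, the same number adjusted over the list alone, among them Selplg, Itgb7, Rgs1 (24.1% against 9.04%) and the chemokine receptor Cxcr3 (22.1% against 9.93%), and 2 fell, Cxcr4 (8.03% against 22.4%) and the integrin chain Itgal (55.4% against 69.2%). Glycolysis and hypoxia genes were lower (adjusted p = 0.0144, but adjusted p = 0.157 with an estimated correlation), and 6 of 12 members fell (8 adjusted over the list alone) and none rose, among them Aldoa (57% against 79.4%), Pkm (67.7% against 83.8%), Mif (37.7% against 59.3%) and Tpi1 (25.3% against 41.0%). On shares of cells, the first 3 of these lists passed at the preset correlation (adjusted p = 0.00278, 0.000645 and 0.00278) but each had an adjusted p = 0.0618 with an estimated correlation, and glycolysis and hypoxia had an adjusted p = 0.190 with an estimated correlation. The myeloid transcript Cst3 also stood higher in Tfr-like than in Tfh-like sums in 5 of 5 units (191 CPM ± 128 against 81.7 CPM ± 31.8), and Lyz2 in 2 of 5. T cell receptor signalling (adjusted p = 0.0546) and immediate early genes (adjusted p = 0.183) did not pass. Of 2 measured helper cytokines and ligands outside the clustering, Lta rose. In the sums edgeR called 0 of 11508 genes, with 674 at an unadjusted p under 0.05 and 568 called by DESeq2. The count by share of cells was 607 without centring, 87 with no replicate block, 208 with equal weights, 422 without plate 1 and 280 without experiment 1.

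**Figure D3:**
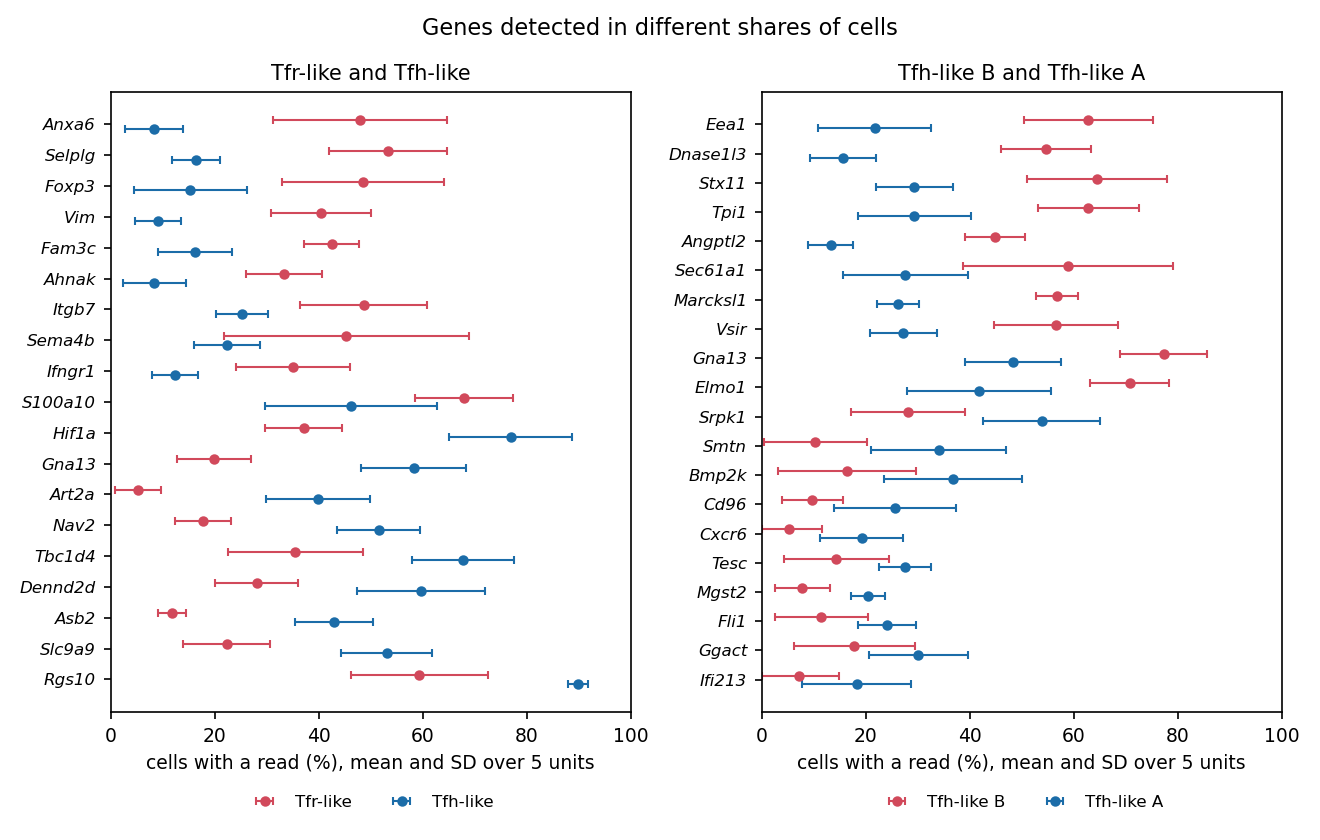
Percent of thinned cells with a read (horizontal axes) for the genes named in the comparison of Tfr-like with Tfh-like cells (left) and of Tfh-like B with Tfh-like A cells (right); points and bars give the mean and SD over 5 units, with bars drawn no lower than 0. Selplg stands at 53.4% in Tfr-like and 16.4% in Tfh-like cells, and Dnase1l3 at 54.7% in Tfh-like B and 15.6% in Tfh-like A cells.

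Tfh-like B and Tfh-like A cells, whose shares per plate followed the labelled Tfh2 and Tfh1 cells, were compared to ask how the 2 kinds of follicular helper cell differ. Genes were found in more cells in Tfh-like B, which had a median of 2129.5 genes per cell against 1694 (median difference over genes 0.0562 on the arcsine scale), and 589 of the 611 genes called without centring went that way (limma, 4977 genes tested). With centring as well, 75 genes were found in more Tfh-like B cells and 22 in fewer. Centring alone called 75 in more and 93 in fewer, so which way most genes went depends on it. The nuclease gene Dnase1l3 (ENSMUSG00000025279, chromosome 14, 7964533 to 7994573) was found in 54.7% ± 8.64 (SD, n = 5) of Tfh-like B and 15.6% ± 6.29 of Tfh-like A cells (adjusted p = 2.56e-15). Also found in more Tfh-like B cells in 5 of 5 units were Eea1, a protein of early endosomes (62.8% against 21.7%), Stx11 (64.5% against 29.4%), Tpi1 (62.8% against 29.3%) and Angptl2 (44.8% against 13.3%). The same held for Sec61a1 of the channel for secreted proteins (58.9% against 27.6%), Marcksl1 (56.8% against 26.2%), the inhibitory receptor gene Vsir (56.6% against 27.2%), Gna13 (77.3% against 48.3%) and Elmo1 (70.7% against 41.8%). Found in fewer Tfh-like B cells were the kinase Srpk1 (28.1% ± 11 against 53.9% ± 11.2, adjusted p = 0.000387), Smtn (10.3% against 34.0%), Bmp2k (16.4% against 36.7%), Cd96 (9.73% against 25.7%) and the chemokine receptor Cxcr6 (5.24% against 19.2%). So were Tesc (14.3% against 27.5%), Mgst2 (7.79% against 20.4%), the transcription factor Fli1 (11.5% against 24.1%), Ggact (17.8% against 30.1%) and Ifi213 (7.23% against 18.2%). At clustering resolution 1, over 4 units without the dsRed unit, the log2 fold in the sums turned for 9 of these 20 genes, Eea1 (-1.37), Tpi1, Angptl2, Marcksl1 (-1.43), Vsir, Smtn, Bmp2k, Cxcr6 and Tesc. There 113 of the 182 Tfh-like B cells were named Tfh-like A, because another cluster had the higher Tfh score. These folds therefore compare other cells under the same names.

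T cell receptor signalling genes were higher in Tfh-like B as a list (adjusted p = 1.64e-05, but adjusted p = 0.107 with an estimated correlation). By share of cells 7 of its 9 measured members rose, 9 adjusted over the list alone, among them the transcription factors Batf (51.3% against 25.1%), Bhlhe40 (24.0% against 3.42%), Egr1 (27.1% against 11.8%) and Egr2 (20.1% against 6.69%). Glycolysis and hypoxia genes were also higher (adjusted p = 1.64e-05, but adjusted p = 0.107 with an estimated correlation), and 8 of 11 members rose (9 adjusted over the list alone), among them Tpi1, Pfkp (45.7% against 24.8%), Pgk1 (44.6% against 28.2%) and Ldha (78.2% against 61.8%). On shares of cells this list passed with an estimated correlation too (adjusted p = 0.0464), and T cell receptor signalling did not (adjusted p = 0.138). With centring, 4 of these 8 named members passed, Batf, Bhlhe40, Egr1 and Tpi1, and Egr2, Pfkp, Pgk1 and Ldha did not. Migration and adhesion genes were lower as a list (adjusted p = 0.0203, but adjusted p = 0.107 with an estimated correlation), with 2 of 9 members down (2 adjusted over the list alone), Cxcr6 and Gpr183 (10.7% against 24.5%), and 1 up (2 adjusted over the list alone), Itgal (76.8% against 66.0%). The IL-2 and STAT5 response (adjusted p = 0.0860), immediate early genes (adjusted p = 0.130) and the interferon response (adjusted p = 0.584) did not pass in the sums, and their mean log2 folds (-0.54, -0.01 and -0.55) lay below 0 where their medians lay above it. On shares of cells, immediate early genes, which also mark the stress of dissociation, were higher in Tfh-like B (adjusted p = 0.0382, but adjusted p = 0.149 with an estimated correlation), with 3 of 9 members up (7 adjusted over the list alone). The IL-2 and STAT5 response was higher as well (adjusted p = 0.0382, but adjusted p = 0.138 with an estimated correlation), with 3 of 6 members up. Of 2 measured inhibitory receptors, Lag3 rose (23.7% against 7.58%). Ighm, a member of the list of B cell markers, had a read in 80.2% of Tfh-like B and 70.9% of Tfh-like A cells, and in 77.6% of CD8-like cells. In the sums edgeR called 0 of 10372 genes, with 373 at an unadjusted p under 0.05 and 265 called by DESeq2. The count by share of cells fell to 168 with centring alone, 167 with equal weights, 46 with no replicate block, 5 at clustering resolution 1 (4 units, against 563 over the same units) and 230, 327 and 391 without experiment 1, experiment 2 or the PA-GFP unit of experiment 4. At resolution 1 the names Tfh-like A and B cover other cells, as given above.

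Resting-like cells, the class with the markers of recirculating T cells, were compared with the Tfh-like cells of the same experiments. By share of cells 638 genes differed both with and without centring, 285 found in more resting-like cells and 353 in fewer (limma, 4500 genes tested, 4 units). Centring alone called 410 in more and 353 in fewer. Tbc1d4, a regulator of vesicle transport (ENSMUSG00000033083, chromosome 14, 101442360 to 101609191), was found in 5.29% ± 6.17 (SD, n = 4) of resting-like and 70.1% ± 9.50 of Tfh-like cells (adjusted p = 3.73e-29). Also found in fewer resting-like cells in 4 of 4 units were Hif1a (20.3% against 76.4%), the survival gene Bcl2a1b (7.71% against 61.2%), Nav2 (2.35% against 54.0%), S100a11 (18.3% against 68.8%) and the tetraspanin Cd82 (24.2% against 74.6%). So were Vmp1 (26.8% against 75.5%), Pear1 (4.04% against 51.0%), Rnaset2b (40.4% against 86.9%) and Cd44, an adhesion receptor of antigen-experienced T cells (11.2% against 56.1%). Selplg was found in 72.0% ± 8.41 of resting-like and 15.3% ± 4.49 of Tfh-like cells (adjusted p = 1.37e-22). Ripor2 (63.9% against 13.5%), Gimap4, a GTPase of lymphocytes (66.9% against 21.9%), Vim (46.5% against 7.23%), the glucocorticoid-induced gene Tsc22d3 (41.2% against 4.14%), Stk38 (54.1% against 17.8%), Itgb7 (57.6% against 23.2%), Anxa6 (40.5% against 6.27%), the IL-4 receptor chain Il4ra (38.0% against 4.79%) and Foxn3 (55.3% against 22.9%) were likewise found in more resting-like cells.

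T cell receptor signalling genes were lower in resting-like cells as a list (adjusted p = 0.0150, but adjusted p = 0.716 with an estimated correlation), with 4 of 7 members down (4 adjusted over the list alone) and none up, among them Batf (6.54% against 32.7%) and Nfatc1 (31.2% against 65.0%). In glycolysis and hypoxia 9 of 12 members fell (9 adjusted over the list alone), among them Aldoa (44.6% against 79.5%) and Gapdh (77.3% against 96.8%), and 1 rose (2 adjusted over the list alone), Pdk1, a kinase that restrains pyruvate use in mitochondria (36.1% against 11.8%). That list did not pass in the sums (adjusted p = 0.592) and passed on shares of cells (adjusted p = 0.00734, but adjusted p = 0.235 with an estimated correlation). The interferon response (adjusted p = 0.592), the IL-2 and STAT5 response (adjusted p = 0.225), migration and adhesion (adjusted p = 0.686) and immediate early genes (adjusted p = 0.686) did not pass either, and camera ranked these 4 lists upward although their median and mean log2 folds lay below 0. Foxp3 was found in 18.1% ± 24.0 of resting-like and 10.8% ± 4.71 of thinned Tfh-like cells (limma adjusted p = 0.0433, higher in 3 of 4 units), a direction that turned without plate 1. In the sums edgeR called 1 of 11128 genes, with 1350 at an unadjusted p under 0.05 and 2503 called by DESeq2. The called gene was C230085N15Rik, named after its values were seen, with 997 CPM ± 258 in resting-like and 26.6 CPM ± 17.8 in Tfh-like cells (log2 fold 5.40, higher in 4 of 4 units, edgeR adjusted p = 0.0114). The count by share of cells was 918 without centring, 89 with no replicate block, 574 without plate 1 and 381 without experiment 1.

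Tfr-like cells were also set against resting-like cells, to separate the regulatory program from the one that both share against Tfh-like cells. In experiment 1, however, 26 of 45 resting-like cells had a Foxp3 read, 25 of them among the 31 on plate 1. Regulatory cells may therefore stand on both sides of this comparison. Both with and without centring 133 genes differed, 80 found in more Tfr-like cells and 53 in fewer (limma, 4334 genes tested, 4 units). Vmp1, a gene of autophagy (ENSMUSG00000018171, chromosome 11, 86583865 to 86683836), was found in 67.1% ± 8.22 (SD, n = 4) of Tfr-like and 26.8% ± 15.7 of resting-like cells (adjusted p = 3.13e-09). Found in more Tfr-like cells in 4 of 4 units were Ndfip1, an adaptor of ubiquitin ligases (67.8% against 31.4%), Cd82 (59.9% against 24.2%), the IL-2 receptor chain Il2rb (58.6% against 24.7%), Ifi27l2a (85.2% against 52.3%) and H2afz (66.3% against 36.4%). So were the activation marker Cd83 (32.4% against 3.08%), Pdia3 (62.2% against 33.0%), Fnbp1 (62.1% against 33.0%) and Glrx (35.3% against 6.29%). Found in fewer were Atp1b3 (41.3% against 76.4%), Ripor2 (30.1% against 63.9%), Crlf3 (31.9% against 61.5%), Stk38 (25.1% against 54.1%) and Ablim1 (48.7% against 73.9%). So were Tsc22d3 (16.8% against 41.2%), the lymphocyte transcription factor Ikzf1 (30.4% against 54.7%), Pdk1 (12.3% against 36.1%), Ms4a4b (65.5% against 88.1%) and Grk6 (10.4% against 32.7%). Foxp3 was found in 47.0% of Tfr-like and 18.1% of resting-like cells (adjusted p = 5.48e-05, 28.9 points ± 10.2). T cell receptor signalling was the 1 list that passed, higher in Tfr-like cells (adjusted p = 0.00582, but adjusted p = 0.236 with an estimated correlation), with 2 of 6 members up (2 adjusted over the list alone), Batf (20.2% against 6.54%) and Nfatc1 (57.4% against 31.2%). On shares of cells it did not pass (adjusted p = 0.0787). Some members of the lists of B cell and myeloid markers moved the same way, with Cd74 in 23.8% ± 14 of Tfr-like and 6.21% ± 8.58 of resting-like cells, Ighm in 70.5% ± 6.72 and 51.2% ± 12.3, and Cst3 in 32.1% ± 6.32 and 21% ± 8.39, each in 4 of 4 units. Lyz2 (5.87% ± 5.12 and 0.556% ± 1.11) and Tyrobp were higher in 3 of 4, and H2-Aa and C1qb in only 1 of 4. The clustering used all of these genes but C1qb, and they are given without a test. Migration and adhesion (adjusted p = 0.307), the IL-2 and STAT5 response and the interferon response (both adjusted p = 0.816), immediate early genes (adjusted p = 0.886) and glycolysis and hypoxia (adjusted p = 0.908) did not pass in the sums. In the sums edgeR called 0 of 9683 genes, with 530 at an unadjusted p under 0.05 and 1031 called by DESeq2. The count by share of cells was 147 without centring, 5 with no replicate block, 113 without plate 1, 36 without experiment 1 and 85 without experiment 3.

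Experiment 5 follows T cells with the OT-II receptor, which recognises ovalbumin, in a strain in which Foxp3 can be switched on in CD4 cells. Of the 2 receptor segments of OT-II, the Trav14 segments were found in 99.5% (95% interval 97.5 to 100) and Trbv12-2 in 86.3% (81.0 to 90.6) of 219 cells, against 11.8% and 13.2% of kept cells in experiments 1 to 4. Pdcd1 was found in 73.5%, Cxcr5 in 59.4%, Bcl6 in 47.9%, Icos and Cd40lg each in 39.3%, Il4 in 27.9%, Il21 in 19.2% and Ctla4 in 18.7% of cells. Il2ra was found in 2.28% and Mki67 in 1.83%. Foxp3 had a read in 66 cells (30.1%, 24.1 to 36.7), between 27.8% and 32% in the 4 sets of columns, with a median of 210.5 reads in these cells. Since 110 cells are labelled as ectopic Foxp3 cells, at least 44 of them (40%) had no Foxp3 read, whichever columns they are. The annotated gene is the 1 Foxp3 row listed for this experiment, and whether reads of the ectopic transcript are all counted there is not known. Ectopic Foxp3 cells and controls were not compared.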

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

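The test with CD8-like cells and the test of a single unit were chosen after their results had been seen; the other tests in this part were set out before. Values were compared within 98 groups of 4 or 5 units, and 6 groups held a unit far from the others, where chance alone gives about 1 in 20.

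Foxp3 reads in Tfh-like cells were found in every unit, in 7.26% to 33.3% of cells. Free RNA or reads from other wells would reach CD8-like cells alike, but in experiments 1 and 2, where 37 of 40 and 25 of 30 CD8-like cells held Cd8a, the CPM of Foxp3 in Tfh-like cells was at least 56.6 times that in CD8-like cells (62.7 times in experiment 1, and at least 31.9 times in experiment 2, with 0 reads in the CD8-like cells of a unit taken as 3), which argues against free RNA as the whole source there. In experiments 3 and 4 the ratio was at least 5.14, but 0 of 7 and 0 of 6 CD8-like cells held Cd8a, so free RNA cannot be told apart there. Tfr-like cells placed in the Tfh-like class could also carry Foxp3. The 197 other genes found in more Tfr-like cells stood in Tfh-like cells at a median of 0.536 of their Tfr-like CPM and Foxp3 at 0.406 (0.507 and 0.247 without the dsRed unit), and the median lay below Foxp3 in only 1 of 5 units, the dsRed unit, so misplaced Tfr-like cells and Foxp3 expression by helper cells cannot be told apart by these classes; the latter is what the title names and was not tested.

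Foxp3 was found in a larger share of Tfh-like B than of Tfh-like A cells. At clustering resolution 1 the difference was -7.18 points over 4 units, without the dsRed unit, against 5.65 points over the same units before. At that resolution 113 of the 182 Tfh-like B cells, 26 of them with Foxp3, were named Tfh-like A. Of the Tfh-like A cells, 75 were named Tfh-like B, 2 of them with Foxp3. The -7.18 points therefore compare other cells under the same names and do not test the difference between the main classes. Tfh-like B cells also showed more genes per cell, which may raise the share for any gene. Among 2245 genes found in a like share of cells, the Foxp3 difference stood at percentile 96.1, past the 95th percentile set beforehand, but at percentile 51.1 without the dsRed unit, so the number of genes per cell cannot be told apart from a difference in Foxp3. A single unit as the whole source cannot be told apart either: the other 4 units had a mean difference of 5.65 points ± 3.60, from 0.714 to 9.37 points, but with Cd79a-positive cells kept it was below 0 in experiment 1 (-5.75 points) and experiment 3 (-8.17 points). The labels name the strain of the dsRed unit, but strain cannot be told apart there from plate or sex. In the clustered classes this unit is plate 12 alone, where 53 of 93 cells are labelled as filtered and 30 held Cd79a. Xist, a transcript of female cells, was found in 30% of its 50 kept cells and in 0 of 155 in the PA-GFP unit. Experiment 2 had Xist in 39.3% of cells and a difference of 6.21 points. A biological difference of the strain stays open and was not tested.

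The values of experiments 1 and 2 include an added Foxp3 sequence, read outside the comparisons. In experiment 1 it had a read in 303 of 384 cells. If these reads followed Foxp3 expression, CD8-like cells should show them as rarely as the annotated gene, but 82.5% of 40 CD8-like cells had a read there, against 10% (95% interval 2.79 to 23.7) for the annotated gene. Most of these reads were few, with a median of 2 in CD8-like and 109.5 in Tfr-like cells, and at 10 reads or more the added sequence was found in 26.0% of cells, like the annotated gene. In experiment 2 it was found in 0 of 30 CD8-like cells, which allows a share of up to 10%. The source of the low reads in experiment 1 was not tested further, and no biological explanation was tested.

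Other values that stood apart are given without an explanation. The share of Tfh-like B cells with Foxp3 was 60% in the dsRed unit of experiment 4 (6 of 10 cells) and at most 23.9% in the other units, and the difference between Tfh-like B and A in that unit was 45.7 points. The share of resting-like cells with Foxp3 was 57.8% in experiment 1 and at most 9.09% in the other units, and on plate 1 of that experiment 67.7% of all 96 wells had a Foxp3 read. The difference between Tfr-like and Tfh-like cells was 56.1 points in experiment 1 and at most 34.4 points elsewhere. Labelled Cycling cells made up 10.5% of the dsRed cells not filtered (6 of 57, those on plate 13 included), the next highest unit having 3.54%. The difference for Cd82 between resting-like and Tfh-like cells was -19.3 points in 1 unit, the nearest other unit lying at -57.4 points. In experiment 5, 66 of 219 cells had a Foxp3 read. On plate 13, which holds both strains and was left out of the units of the clustered classes, 25 of 70 kept cells had one.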

How the results depend on the processing

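The alternatives with Cd79a-positive cells, clustering resolution 1, variable genes, the added Foxp3 sequence, plate 1 and averages over plates, and all tests by share of cells, were chosen after seeing the data. Comparisons below are in the order Tfr-like against Tfh-like, Tfh-like B against A, resting-like against Tfh-like and Tfr-like against resting-like. In the sums edgeR called 0, 0, 1 and 0 genes. DESeq2 called 568, 265, 2503 and 1031, no filter gave 5, 1, 44 and 5, and all 4 classes in one fit gave 3, 0, 167 and 18. No replicate block gave 4, 0, 21 and 0. Means of CPM per cell gave 3, 0, 848 and 0 at a pseudocount of 1, and 8, 0, 541 and 0 at 10. Size factors of DESeq2 gave 21 and thinned cells 49 genes for resting-like against Tfh-like and 0 elsewhere. Keeping Cd79a-positive cells gave 1 gene in Tfr-like against Tfh-like and 2 in resting-like against Tfh-like, and the latter comparison gave 0 at clustering resolution 1, 0 without plate 1 and from 0 to 3 without single units. The cause of these differences was not tested, though fewer units or genes enter where units or plates are left out.

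By share of cells, limma called 607, 611, 918 and 147 genes. Leaving out single units gave 280 to 584, 230 to 563, 381 to 779 and 36 to 121, each time lowest without experiment 1. Tfh-like B against A also fell without experiment 2 (327) and without the PA-GFP unit (391), and Tfr-like against resting-like without experiment 3 (85). No replicate block gave 87, 46, 89 and 5. Equal weights gave 208 and 167 in the first 2 comparisons. Tfh-like B against A gave 168 with each sum centred, as the higher number of genes per cell is then removed, and 5 at clustering resolution 1, over 4 units that gave 563 in the main classes. At that resolution most of the Tfh-like B cells carried the name Tfh-like A. Without plate 1 the counts were 422, 591, 574 and 113. Of the fixed lists, camera called 4, 3, 1 and 1. With an estimated correlation it called 3, 0, 0 and 0, and on shares of cells it called 5 in the second, 2 in the third and 0 in the last comparison.

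The Foxp3 difference between Tfr-like and Tfh-like cells kept its sign in every alternative, and so did Tfh-like B minus A except at clustering resolution 1, where it was -7.18 points over 4 units; the dsRed unit had too few Tfh-like B cells there (3), and the same 4 units had 5.65 points in the main classes. With Cd79a-positive cells kept, Tfh-like B minus A was 5.85 points and positive in 3 of 5 units. At clustering resolution 1, the Tfr-like name went to clusters of 123 and 67 cells. Clusters of 72 and 73 cells had no name, the second with Lyz2 and H2-Aa among its 10 leading genes. Of the 182 Tfh-like B cells, 113 (23% of them with Foxp3) were named Tfh-like A there, because another cluster had the higher Tfh score. Under the same naming the log2 folds of named genes turned for Angptl2 (-0.85), Vsir (-0.71), Tpi1 (-0.083), Eea1 (-1.37), Marcksl1 (-1.43), Foxp3 (-3.67), Smtn (0.42), Tesc (0.18), Bmp2k (0.27) and Cxcr6 (0.78). Resting-like minus Tfh-like turned to -5.11 points without plate 1, -3.36 when differences were averaged over plates and -2.53 without experiment 1. The log2 fold of Foxp3 turned with it to -2.52 without plate 1 and -0.53 with means of CPM at a pseudocount of 1, and ranged from -0.20 (without experiment 1) to 1.64 without single units. No named gene passed the threshold in the sums by edgeR, so staying on that side says nothing about stability. Over 1369 settings of 83 named gene results, 140 passed it and 13 turned. With filtered cells in the denominator, Tfh1 made up 23.3%, Tfh2 15.8% and Tfr 11%. The other settings chosen in advance for ectopic Foxp3 against control cells were not run, since that comparison was not made. Depth limits single cells: a gene without a read at 50000 reads may still be expressed, and 27 cells were too shallow to thin.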

Other observations

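All tests in this part that use shares of cells, and the count of lists in Tfr-like against Tfh-like cells, were chosen after their results had been seen. Cycling-like cells, the smallest class with 45 cells, had the highest number of genes, with a median of 3010. Mki67, a marker of dividing cells, was found in 43.6% ± 24.6 (SD, n = 5) of them, and in at most 3.61% of Tfr-like, Tfh-like A and Tfh-like B cells on average. Bcl6 was found in 38.3% ± 13.8 and Pdcd1 in 55.9% ± 18 of cycling-like cells, and Foxp3 in 13 of 45 (28.9%, 95% interval 16.4 to 44.3). Without the dsRed unit, where 8 of 12 had a Foxp3 read, it was found in 5 of 33 (15.2%, 5.11 to 31.9). They also held transcripts of antigen-presenting cells, with Cd74 in 66.7% and the macrophage gene Lyz2 in 31.1% of cells, against 17% and 4.16% of Tfh-like cells. Mki67, Bcl6, Pdcd1, Cd74 and Lyz2 are given without a test, since the clustering used them. Of the 45 cells 12 came from the dsRed unit of experiment 4, 24.0% of its kept cells.

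Markers of other cell types were found in every class. Cst3 was found in 20% to 62.2% and Cd74 in 8% to 66.7% of the cells of each class, and Ighm in 55.0% to 80.2%. Cst3 stood higher in Tfr-like than in Tfh-like sums in 5 of 5 units, Tyrobp in 3, Lyz2 in 2 and C1qb in 1. In experiment 2 Lyz2 reached 1379 CPM in Tfr-like and 31.8 CPM in Tfh-like cells. These values are given without a test. Cd79b was found in 1.63% of Tfh-like, 4.01% of Tfr-like and 11.8% of CD8-like cells, and was itself used in the clustering. The plasma cell gene Jchain was found in 1.99% of Tfh-like and 2.55% of Tfr-like cells, the stromal chemokine Cxcl13 in 1.08% and 0.365%, and the globin gene Hbb-bs in 1.45% and 2.92%. Transcripts of the X and Y chromosomes differed between units. Xist, which is expressed from the inactive X chromosome of female cells, was found in 39.3% of cells in experiment 2 and 30.0% in the dsRed unit, in 0.881% in experiment 3 and in 0 of 326 cells in experiment 1, which allows a share of up to 0.920%. In the PA-GFP unit of experiment 4 it was found in 0 of 155 cells, which allows a share of up to 1.94%. The Y-linked gene Eif2s3y was found in 33.7% of cells in experiment 1, 7.86% in experiment 2, 22.5% in experiment 3, 20% in the PA-GFP unit and 26.0% in the dsRed unit of experiment 4.

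The calls were set against other splits of the same sums. By share of cells the real split gave the most genes in all 4 comparisons, but the classes were clustered from the same cells, which favours the real split by construction, so this test does not decide on chance. In Tfr-like against Tfh-like 1 of 100 splits, the real one, gave as many as 607 genes, the highest of the others giving 453. In Tfh-like B against A 1 of 100 splits gave 611, the highest other 408. In resting-like against Tfh-like 1 of 32 gave 918, the highest other 347, and in Tfr-like against resting-like 1 of 32 gave 147, the highest other 77. Many of these splits part only some of the pairs and can hold the real contrast on those pairs. The splits that part every pair, 16, 16, 8 and 8 in turn, are too few for a share under 5%, and the highest other than the real one gave 453, 344, 0 and 24 genes.

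By edgeR the real count was 0 genes in 3 comparisons, so every split gives as many and the splits decide nothing there. The highest other split gave 817 genes in Tfr-like against Tfh-like (35 of 35 splits with 0 or more), 911 in Tfh-like B against A (35 of 35) and 0 in Tfr-like against resting-like (32 of 32). In the first 2 comparisons a single split gave these genes and every other gave 0. It parts only the dsRed unit, so its difference rests on 1 pair of sums. These hold 24 Tfh-like and 11 Tfr-like cells in the first comparison, and 14 Tfh-like A and 10 Tfh-like B cells in the second. A single pair of small sums does not allow a conclusion, and the cause was not tested. In resting-like against Tfh-like 3 of 32 splits gave 1 gene or more, the highest other 1. The others that gave a gene part only 2 pairs and hold the real contrast on these pairs. Of the 8 splits that part every pair, 1 gave a gene, the real one. As 8 splits are too few for a share under 5%, chance cannot be excluded. The number of lists called by camera does not decide on chance either. Many of the splits part only some of the pairs and can hold the real contrast on fewer units. Of the splits that part every pair, 1 of 14, 2 of 14, 1 of 8 and 1 of 8 gave as many lists, the real one included. These splits are too few for a share under 5%. The counts over all splits, given next, include those that part only some pairs. Of 100 splits 5 gave as many as the 4 lists of Tfr-like against Tfh-like (highest other 4) and 6 as many as the 3 of Tfh-like B against A (highest other 3). Of 32 splits 3 gave as many as the 1 of resting-like against Tfh-like (highest other 1) and 5 as many as the 1 of Tfr-like against resting-like (highest other 3).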
